A study of Mus musculus with 10 samples.

How the data were processed

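RNA sequencing libraries of 10 CT26 tumours were analysed, 4 labelled sgEV, 3 labelled sgMEN1-1 and 3 labelled sgMEN1-3, with each library's group taken from its label. The deposited values are raw read counts per gene symbol made by the authors with STAR 2.4.2a and HTSeq 0.11.0, per the submitters' processing notes, which do not give each tool's role. The counts are whole numbers with a different total in each library and no normalization. Each file holds 55228 gene symbols and 5 summary lines for reads not assigned to a gene, which were left out of totals and tests and took 18.8% to 23.7% of the reads. The notes list the human build hg38, although the symbols are those of mouse genes, so the build and annotation are uncertain and no positions are given. The strand setting is not stated. Reads that matched more than one place were not counted, which makes values of gene families such as Pcdhb, MHC, granzyme and immunoglobulin genes uncertain.

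Library totals ran from 20351813 to 43070830 gene counts. The 50 most abundant genes took 13.1% to 15.5% of them. Counting error was small beside the spread between tumours. Within groups the chi-square per degree of freedom between libraries was 14.3 to 149, where counting error alone gives about 1.

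Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the groups (17386 genes), library sizes were scaled by TMM, and a quasi-likelihood model with 3 group means was fitted to all 10 libraries (glmQLFit, glmQLFTest). The main contrast was the mean of both Men1 guides minus sgEV, so that each guide has the same weight. The others were each guide minus sgEV and sgMEN1-3 minus sgMEN1-1. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. Group values are the mean and SD of CPM on TMM-scaled library totals, and fold changes, with their standard errors, come from edgeR unless DESeq2 is named. A log2 CPM used a prior count of 2. Men1 was also tested by a two-sided exact permutation test of log2 CPM over all splits of 4 and 6 libraries.

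A set of 35 gene lists, 20 of processes and 15 of cell types, with 620 tested genes in all, was written from general knowledge before the data were examined, as were the comparisons, tests, alternatives and the rule for naming genes. Lists were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation between genes of 0.01, adjusted over the 35 lists. A list's score in a library is the mean over its genes of log2 CPM centred on the gene's mean. Medians and means of a list are over edgeR log2 fold changes. Camera works on log2 CPM and the medians on edgeR fold changes, so their signs can differ. Members were also counted past an adjusted p of 0.05 over all genes and adjusted over the list alone. Some genes belong to more than 1 list, among them Ciita, Cd274, Cxcl9, Hdc and Tcf7.

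Named genes are Men1; the 10 largest log2 fold changes each way among genes past the threshold in the main contrast, with a mean log2 CPM of at least 1, no predicted gene model and the same sign with both guides; the 5 largest each way in each other contrast; and up to 3 members of each list with the smallest p in the main contrast. The threshold parts named 0 genes and the list part 101, of which the text gives a selection made after their values were seen. List members picked by smallest p tend to have larger fold changes than the rest of their list. Genes named on other grounds are said to have been chosen after their values were seen.

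The correlation of the guide effects was compared with 50 simulations without a guide effect, which keep the shared sgEV libraries, and with 6 assignments of the sgEV libraries to the guides in pairs. The models were tested on simulated data with 200 changed genes per run. All simulations drew genes independently of each other, with the same spread in all groups. They lack the differences between tumours that many genes share, so the recovered shares do not measure power in these data. At changes of 2, 4 and 8 times, 51%, 85% and 92% were recovered in the main contrast and 38%, 70.5% and 90.5% with sgMEN1-1. With sgMEN1-3 they were 41.5%, 71% and 91%, and between the guides 38%, 73% and 91%. A simulated shift of 1 on the log2 scale in the interferon-gamma list gave a mean of 0.94 and called 0 other lists. With independent genes this does not measure false calls in real tumours. There the median estimated correlation within lists was 0.283, and other splits of the tumours in the main contrast called a median of 11 lists. A simulated guide covariance of 0.0903 was recovered as 0.0916.

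Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter at a CPM of 1 in 3 libraries, an absolute log2 fold change of 1, the replicate number as a block, fits on the compared groups only, pooled sgMEN1 libraries, and leaving out each library. For lists they were camera with an estimated correlation, fry, RLE, the block, each guide alone and, for the main contrast, leaving out each library. Fits without a library filtered genes and estimated the spread anew, so a library outside a contrast can also change a call. Added after the data were seen were leaving out each library for the lists called in the other contrasts, a fit without the 2 libraries rich in muscle transcripts, robust quasi-likelihood and an exact permutation test of list scores. Gene and list counts were recomputed for other splits of the libraries into groups of the same sizes, 100 drawn for the main contrast and all 35, 35 and 10 for the others.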

Results

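Messenger RNA was profiled in 10 tumours grown in BALB/c mice from CT26, a mouse colon carcinoma line. Cells carrying a lentiviral guide labelled sgEV gave 4 tumours (replicates 2, 3, 4 and 6). Each of the Men1 guides gave 3 tumours, sgMEN1-1 (replicates 1, 3 and 4) and sgMEN1-3 (replicates 2, 3 and 4). The labels do not say that each tumour came from a separate animal, so the p-values measure only the spread between samples. In the sgEV group the reads assigned to genes came to 34807266 in replicate 2, 43070830 in replicate 3, 39300701 in replicate 4 and 40682543 in replicate 6. The sgMEN1-1 libraries held 20351813 in replicate 1, 42822155 in replicate 3 and 33747542 in replicate 4. The sgMEN1-3 libraries held 32494881 in replicate 2, 38406111 in replicate 3 and 31844886 in replicate 4. A count was seen for 31974 gene symbols in some library, and 17386 were abundant enough to test.

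The sgEV tumours were less alike than the tumours of either Men1 guide. Across genes, log2 CPM (gene counts relative to the scaled library total, on the log2 scale) correlated with r = 0.957 to 0.977 between sgEV libraries, 0.983 to 0.987 between sgMEN1-1 libraries and 0.980 to 0.988 between sgMEN1-3 libraries. Between groups the range was 0.959 to 0.986, so the libraries did not separate by group. The main axis of a principal component analysis held 30.9% of the variance and set sgEV replicates 3 and 4 (scores 50.5 and 69.8) apart from sgEV replicate 2 (score -39.4). The 6 sgMEN1 libraries lay between -31.3 and 17.7 on the same axis. Skeletal muscle transcripts marked a different pair of tumours. The muscle list scored 2.44 in sgEV replicate 6 and 3.00 in sgMEN1-1 replicate 3, against 0.77 or less in the other libraries, with Ckm, the muscle creatine kinase, at 12.9 and 13.3 CPM.

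The Men1 transcript was not reduced in the tumours labelled as Men1 knockout. Men1 encodes menin, a nuclear scaffold of MLL histone methyltransferase complexes. In sgEV tumours Men1 stood at 25.6, 17.8, 22.4 and 16.6 CPM in replicates 2, 3, 4 and 6, a mean of 20.6 ± 4.16 (SD, n = 4). It stood at 25.0, 26.5 and 24.4 CPM in sgMEN1-1 replicates 1, 3 and 4, a mean of 25.3 ± 1.08 (n = 3). In sgMEN1-3 replicates 2, 3 and 4 it stood at 18.9, 23 and 20.5 CPM, a mean of 20.8 ± 2.07 (n = 3). The log2 fold change of the 2 guides together against sgEV was 0.15 (SE 0.13, 95% interval -0.14 to 0.45; edgeR adjusted p = 0.828). A two-sided exact permutation test of log2 CPM over 210 splits gave p = 0.257. For sgMEN1-1 alone the log2 fold change was 0.29 (SE 0.16, adjusted p = 0.792), and for sgMEN1-3 alone 0.01 (SE 0.16, adjusted p = 0.992). The guides differed by -0.28 (SE 0.17, adjusted p = 0.873). Because Men1 mRNA was not lower, the groups are named by their labels, and each direction given for a gene refers to the libraries labelled sgMEN1-1 or sgMEN1-3. A guide that shifts the reading frame can leave mRNA in place, and mRNA counts do not measure menin protein.

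**Figure D1:**
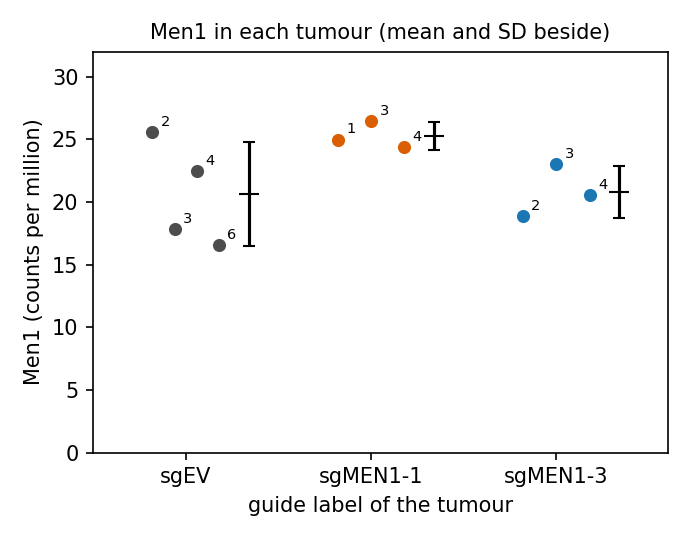
Men1 in each tumour, in CPM (vertical axis), by group (horizontal axis); points are tumours, and the bar with its error shows the mean and SD. The sgEV tumours span 16.6 to 25.6 CPM, sgMEN1-1 tumours 24.4 to 26.5 and sgMEN1-3 tumours 18.9 to 23.

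The series sets wild-type tumours against Men1-knockout tumours. On average the tumours labelled sgMEN1 had more transcript of interferon-response, antigen-presentation, cell-cycle and cholesterol genes than the sgEV tumours. They had less transcript of some epithelial genes and, with sgMEN1-1 but not with sgMEN1-3, of fibroblast genes. The fibroblast list scored -0.75 and -0.81 in sgMEN1-1 replicates 1 and 4. It scored -0.14 to 0.27 in the other sgMEN1 tumours and 0.09 to 0.62 in sgEV tumours. These shifts were averages over groups of genes that passed camera at a preset correlation, and 0 of the 35 groups passed with an estimated correlation, with fry or with permutation. No gene taken alone passed in edgeR with its filter on low counts, while DESeq2 called 5 and edgeR without a filter 2. In the interferon, antigen-presentation, cholesterol and epithelial groups sgEV replicates 3 and 4 lay farthest from the sgMEN1 tumours, while sgEV replicate 2 resembled them.

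With edgeR, 0 of the 17386 genes passed an adjusted p of 0.05 in the contrast of both guides with sgEV, and the smallest adjusted p was 0.813. At an unadjusted p under 0.05 edgeR gave 927 genes (274 higher and 653 lower with the Men1 guides), where 869 are due by chance. That count was 3348 without sgEV replicate 2, 514 without sgEV replicate 3, 553 without sgEV replicate 4 and 570 without sgMEN1-1 replicate 1. Among 100 splits of the tumours into groups of the same sizes, the real one included, 35 gave at least 927 genes. Limma-voom gave 0 genes, with 861 at an unadjusted p under 0.05. DESeq2 called 5 genes, which are named here after their values were seen. Ccl11, an eosinophil-attracting chemokine of stromal cells, averaged 11.7 ± 5.18 CPM (n = 4) in sgEV and 2.94 ± 1.49 (n = 6) in sgMEN1 tumours, and its DESeq2 log2 fold change was -1.997 (adjusted p = 0.000319). Crabp1, a retinoic acid binding protein, went from 1.37 ± 0.66 to 0.406 ± 0.305 CPM (DESeq2 log2 fold change -2.18, adjusted p = 0.00604). Dnase1l3, a nuclease secreted by myeloid cells, went from 5.38 ± 2.30 to 14.8 ± 5.68 CPM (1.43, adjusted p = 0.00604). Slc40a1, the iron exporter ferroportin, went from 2.23 ± 0.306 to 4.43 ± 1.27 CPM (0.96, adjusted p = 0.0127). Krt8, a keratin of simple epithelia, was high in sgEV replicates 3 and 4 alone (146 and 246 CPM). It stood at 0.636 and 0.925 CPM in sgEV replicates 2 and 6 and at no more than 2.61 CPM in any sgMEN1 tumour (DESeq2 log2 fold change -6.80, adjusted p = 0.00604). In edgeR all 5 of these genes had an adjusted p of 0.813.

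Groups of genes were tested with camera on 35 lists, of which 17 passed an adjusted p of 0.05, 14 higher and 3 lower in the sgMEN1 tumours. Camera was run with a small preset correlation between genes. With an estimated correlation, and with fry, 0 lists passed, and 1 list had an unadjusted p under 0.05 by each. An exact permutation test of the list scores, added after the data were seen, also passed 0 lists after adjustment, and its smallest p was 0.0333. Over all genes 0 list members passed in edgeR, and 7 passed when adjusted over the list alone, 4 in the matrix remodelling list and 3 in the colon epithelium list.

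**Figure D2:**
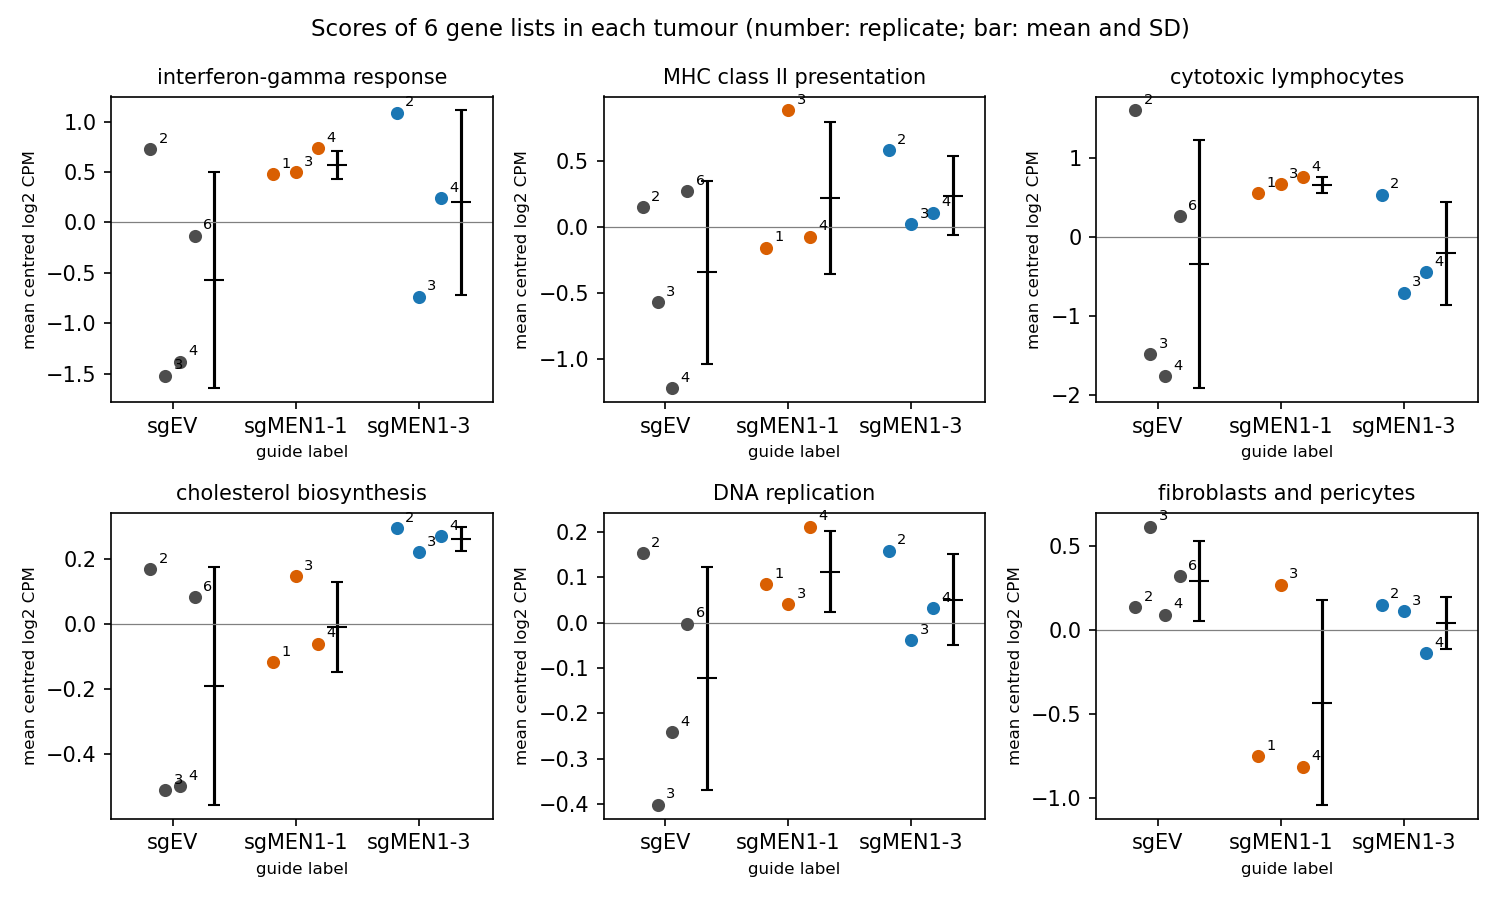
Scores of 6 gene lists in each tumour, as the mean of centred log2 CPM over the list (vertical axis) by group (horizontal axis); numbers are replicates, and bars show mean and SD. For the interferon-gamma list sgEV tumours span -1.52 to 0.73 and sgMEN1 tumours -0.73 to 1.09.

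Interferon-gamma response genes were higher in the sgMEN1 tumours, and with them the genes that load and display peptides on MHC molecules. Interferon-gamma, released by activated lymphocytes, induces Cxcl9, a chemokine that draws T cells, Ciita, the switch for MHC class II genes, and the checkpoint ligand Cd274 (PD-L1). Of 26 interferon-gamma response genes 25 had a positive log2 fold change, with a median of 0.79 (camera adjusted p = 1.72e-08; adjusted p = 0.580 with an estimated correlation). The list scored 0.73, -1.52, -1.38 and -0.13 in sgEV replicates 2, 3, 4 and 6, and from -0.73 to 1.09 in the sgMEN1 tumours. Cxcl9 averaged 81.0 ± 30.9 CPM (n = 4) in sgEV and 163 ± 44.8 (n = 6) in sgMEN1 tumours, a log2 fold change of 1.00 (SE 0.26, edgeR adjusted p = 0.813). Ciita stood at 7.26 ± 5.24 and 15.8 ± 5.83 CPM (1.12, SE 0.47, adjusted p = 0.813). Ido1, which breaks down tryptophan, stood at 1.503 ± 1.70 and 4.10 ± 2.58 CPM, and Cd274 at 43.3 ± 24.1 and 65.9 ± 22.1 CPM. Of 22 MHC class I presentation genes 19 were positive, with a median of 0.42 (adjusted p = 3.99e-06; adjusted p = 0.580 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, stood at 104 ± 56.0 CPM in sgEV and 163 ± 44.5 in sgMEN1 tumours, with log2 fold changes of 0.61 for Tapbpl and 0.40 for the trimming peptidase Erap1. Of 13 MHC class II genes 12 were positive, with a median of 0.62 (adjusted p = 0.000139; adjusted p = 0.580 with an estimated correlation). Among them H2-DMa had a log2 fold change of 0.48 and H2-DMb2 of 0.62, both with an adjusted p of 0.813. Counts of MHC paralogs are uncertain, since reads matching several genes were not counted. Of 33 type I interferon-stimulated genes 32 were positive, with a median of 0.31 (adjusted p = 5.15e-06; adjusted p = 0.580 with an estimated correlation). Oasl2 stood at 137 ± 109 and 229 ± 99.2 CPM, Parp14 at 53 ± 39.6 and 80.4 ± 21.6 CPM, and Irf9, part of the receptor's transcription factor, at 41.7 ± 21.6 and 56.5 ± 14.9 CPM. Cytosolic nucleic acid sensors were positive in 11 of 14 genes, with a median of 0.23 (adjusted p = 0.0257; adjusted p = 0.580 with an estimated correlation). The DNA sensor Aim2 went the other way, at 59.4 ± 12.6 and 46.3 ± 8.43 CPM (-0.37, SE 0.15).

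Single libraries weighed on these interferon lists. The type I list differed by 0.49 in mean log2 CPM between sgMEN1 and sgEV tumours, by 0.83 without sgEV replicate 2, 0.29 without sgEV replicate 3, 0.25 without sgEV replicate 4 and 0.32 without sgMEN1-3 replicate 2. Without sgEV replicate 4 the difference went from 0.50 to 0.25 for MHC class I and from 0.57 to 0.28 for MHC class II. Nucleic acid sensing differed by 0.29, and by 0.47 without sgEV replicate 2. Its call was lost without sgEV replicate 3 (difference 0.17, adjusted p = 0.301), sgEV replicate 4 (adjusted p = 0.0653), sgEV replicate 6 (adjusted p = 0.0698) or sgMEN1-3 replicate 2 (adjusted p = 0.0977).

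Except for B and plasma cells, leukocyte lists also scored higher in most sgMEN1 tumours than in sgEV replicates 3 and 4. T cell genes were positive in 19 of 22, with a median log2 fold change of 0.35 (adjusted p = 0.000535; adjusted p = 0.580 with an estimated correlation). Cd2, an adhesion receptor of T cells, stood at 1.62 ± 0.867 CPM in sgEV and 2.46 ± 0.441 in sgMEN1 tumours. Tcf7, a transcription factor of naive and memory T cells and of Wnt signalling, went the other way, from 10.7 ± 9.23 to 4.85 ± 2.13 CPM. Neutrophil genes were positive in 14 of 17, with a median of 0.43 (adjusted p = 3.80e-05; adjusted p = 0.580 with an estimated correlation). Hdc, which makes histamine, stood at 3.92 ± 1.28 and 6.51 ± 1.20 CPM (0.73, SE 0.25), and the decoy receptor Il1r2 at 2.24 ± 0.47 and 3.12 ± 0.516 CPM. For cytotoxic lymphocytes the test pointed higher (adjusted p = 0.00646; adjusted p = 0.592 with an estimated correlation), while the median and the mean of the edgeR log2 fold changes were -0.06 and -0.14 and 13 of 22 genes were negative. On the mean of log2 CPM the same list differed by 0.57, since it scored 1.60, -1.48, -1.76 and 0.26 in sgEV replicates 2, 3, 4 and 6. Klrk1, an activating receptor of natural killer and CD8 T cells, stood at 6.07 ± 2.31 CPM in sgEV and 9.14 ± 2.41 in sgMEN1 tumours, and Nkg7, a granule protein, at 8.55 ± 5.61 and 12.2 ± 4.38. Monocyte and macrophage genes had a median of 0.15 (21 of 27 positive, adjusted p = 0.0455; adjusted p = 0.580 with an estimated correlation). Among them Mrc1, the mannose receptor, stood at 98.0 ± 19.1 and 123 ± 30.7 CPM, and Spp1, which encodes osteopontin, at 10149 CPM in sgEV replicate 4 and 3013 to 4135 CPM in the other sgEV tumours. Dendritic cell genes had a median of 0.23 (9 of 15 positive, adjusted p = 0.0395; adjusted p = 0.580 with an estimated correlation). Endothelial genes had a median of 0.18 (15 of 18 positive, adjusted p = 0.0130; adjusted p = 0.580 with an estimated correlation), with Robo4, a receptor of vessel lining, at 15.4 ± 3.71 and 20.3 ± 2.99 CPM.

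Several of these leukocyte calls rested on few tumours. The T cell call was lost without sgEV replicate 4 (difference of mean log2 CPM 0.14 instead of 0.45, adjusted p = 0.244), and the difference was 0.71 without sgEV replicate 2. The cytotoxic call was lost without sgEV replicate 3 (0.19, adjusted p = 0.365), sgEV replicate 4 (0.10, adjusted p = 0.757) or sgMEN1-3 replicate 2 (0.39, adjusted p = 0.0974), and the difference was 1.22 without sgEV replicate 2. For neutrophils the difference of 0.43 became 0.66 without sgEV replicate 2 and 0.27 without sgEV replicate 4. The calls for monocytes and macrophages, dendritic cells and endothelium were each lost without sgEV replicate 3, sgEV replicate 4, sgMEN1-1 replicate 3 or sgMEN1-3 replicate 2. In those fits the adjusted p was 0.179 to 0.983 for monocytes and macrophages, 0.0977 to 0.438 for dendritic cells and 0.0589 to 0.244 for endothelium. Without sgEV replicate 3 camera's direction turned lower for monocytes and macrophages, and the difference of mean log2 CPM was 0.01 instead of 0.14. Without sgEV replicate 2 it was 0.21. For dendritic cells the difference of 0.28 became 0.47 without sgEV replicate 2 and 0.10 without sgEV replicate 4 (adjusted p = 0.438). For endothelium it went from 0.16 to 0.04 without sgEV replicate 4.

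On average cell-cycle and sterol genes were higher in the sgMEN1 tumours, by small steps shared by nearly all genes of each list but not by all tumours. The mitotic list scored -0.12 in both sgMEN1-3 replicates 2 and 4, inside the sgEV range of -0.15 to -0.01. The cholesterol list scored -0.12, 0.15 and -0.06 in sgMEN1-1 replicates 1, 3 and 4. In sgEV replicates 2, 3, 4 and 6 it scored 0.17, -0.51, -0.50 and 0.08. All 24 DNA replication genes were positive, with a median log2 fold change of 0.19 (adjusted p = 2.24e-06; adjusted p = 0.580 with an estimated correlation). Pole, the catalytic subunit of the leading-strand polymerase, stood at 76.5 ± 8.78 CPM (n = 4) in sgEV and 95.8 ± 10.3 (n = 6) in sgMEN1 tumours (0.32, SE 0.11), and the nuclease Fen1 at 30.6 ± 5.70 and 37.6 ± 5.48. Rrm2, which makes deoxynucleotides, stood at 104 ± 24.3 and 127 ± 12.8 CPM. Mitotic genes were positive in 23 of 24, with a median of 0.16 (adjusted p = 1.83e-05; adjusted p = 0.580 with an estimated correlation). Kif11, a spindle motor, stood at 31.3 ± 3.96 and 39.6 ± 6.26 CPM. Mki67, a marker of cycling cells, stood at 340 ± 126 and 443 ± 32.9 CPM, with sgEV replicate 2 at 519 CPM, above every sgMEN1 tumour. Cholesterol biosynthesis genes were positive in 19 of 19, with a median of 0.30 (adjusted p = 3.25e-07; adjusted p = 0.580 with an estimated correlation). Srebf2, the transcription factor of the pathway, stood at 191 ± 36.4 and 236 ± 10.6 CPM (0.30, SE 0.12). The pathway enzyme Lss stood at 31.3 ± 6.97 and 39.5 ± 4.599 CPM. These genes each had an edgeR adjusted p of 0.813. The DNA replication difference of 0.20 in mean log2 CPM became 0.12 without sgEV replicate 3, and the mitotic difference of 0.16 became 0.10 without sgMEN1-3 replicate 3.

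Fibroblast and stress-response genes were called lower in the contrast of both guides, but each with a single guide when the guides were tested apart. With sgMEN1-3 alone fibroblast genes were positive in 11 of 20, with a median of 0.04 (adjusted p = 0.523), and with sgMEN1-1 alone the stress list was not called (median -0.05, adjusted p = 0.986). With both guides together fibroblast and pericyte genes were negative in 17 of 20, with a median log2 fold change of -0.27 (adjusted p = 0.000815; adjusted p = 0.580 with an estimated correlation). Col3a1, a fibrillar collagen, stood at 658 ± 243 CPM in sgEV and 318 ± 161 in sgMEN1 tumours (-1.05, SE 0.36), and Postn, which encodes the matrix protein periostin, at 53.1 ± 31.4 and 15.7 ± 12.3 CPM. Fbln1 stood at 4.61 ± 1.96 and 1.65 ± 1.02 CPM. The list for epithelial-mesenchymal change and matrix remodelling was not called (13 of 24 negative, median -0.15, adjusted p = 0.0806), though it was with the replicate number as a block (adjusted p = 0.0415). Adjusted over the list alone, 4 of its genes passed. Mmp9, a matrix protease, stood at 73.0 ± 38.4 and 25.1 ± 10.0 CPM (-1.54, SE 0.38), and Lox, which crosslinks collagen, at 24.6 ± 16.0 and 7.82 ± 3.34 CPM (-1.65, SE 0.41). The protease Mmp2 had a log2 fold change of -1.34. Tnc, a matrix glycoprotein, had a log2 fold change of -2.49 (SE 0.64), set by 357 and 1237 CPM in sgEV replicates 3 and 4, against 60.3 to 98.5 CPM in the other tumours. Genes of the unfolded protein and amino acid stress response were negative in 15 of 20, with a median of -0.15 (adjusted p = 0.0422; adjusted p = 0.580 with an estimated correlation). Ddit3, a transcription factor of that response, stood at 142 ± 63.1 and 94.5 ± 13.9 CPM, and its partner Trib3 at 86.1 ± 54.9 and 55.3 ± 9.53. The stress difference of -0.12 in mean log2 CPM became -0.21 without sgEV replicate 2. Its call was lost without sgEV replicate 3 (adjusted p = 0.0503), sgEV replicate 4 (-0.05, adjusted p = 0.192), sgEV replicate 6 (adjusted p = 0.282), sgMEN1-1 replicate 3 (-0.06, adjusted p = 0.394), sgMEN1-3 replicate 2 (adjusted p = 0.139) or sgMEN1-3 replicate 4 (adjusted p = 0.0699), and also with the replicate number as a block (adjusted p = 0.103).

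Colon epithelium markers were lower on average in the sgMEN1 tumours, and the list scored highest in sgEV replicates 3 and 4. It scored -0.71, 1.00, 1.98 and 0.29 in sgEV replicates 2, 3, 4 and 6, and -0.54 to -0.28 in the sgMEN1 tumours. All 9 tested genes of the list were negative, with a median of -0.83 (adjusted p = 0.00101; adjusted p = 0.543 with an estimated correlation). The exact permutation test of the list score gave p = 0.0333 before adjustment. Adjusted over the list alone, Krt8, Muc2 and Krt18 passed. Muc2, the secreted mucin of goblet cells, stood at 37.4 CPM in sgEV replicate 4 and 0.166 to 2.53 CPM in the other sgEV tumours, against 0.569 ± 0.468 CPM in sgMEN1 tumours. Krt18, the partner keratin of Krt8, stood at 9.29, 44.8, 83.8 and 25.7 CPM in sgEV replicates 2, 3, 4 and 6, against 15.5 ± 4.74 CPM in sgMEN1 tumours (-1.46, SE 0.43). The list difference of -1.06 in mean log2 CPM became -0.62 without sgEV replicate 4.

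**Figure D3:**
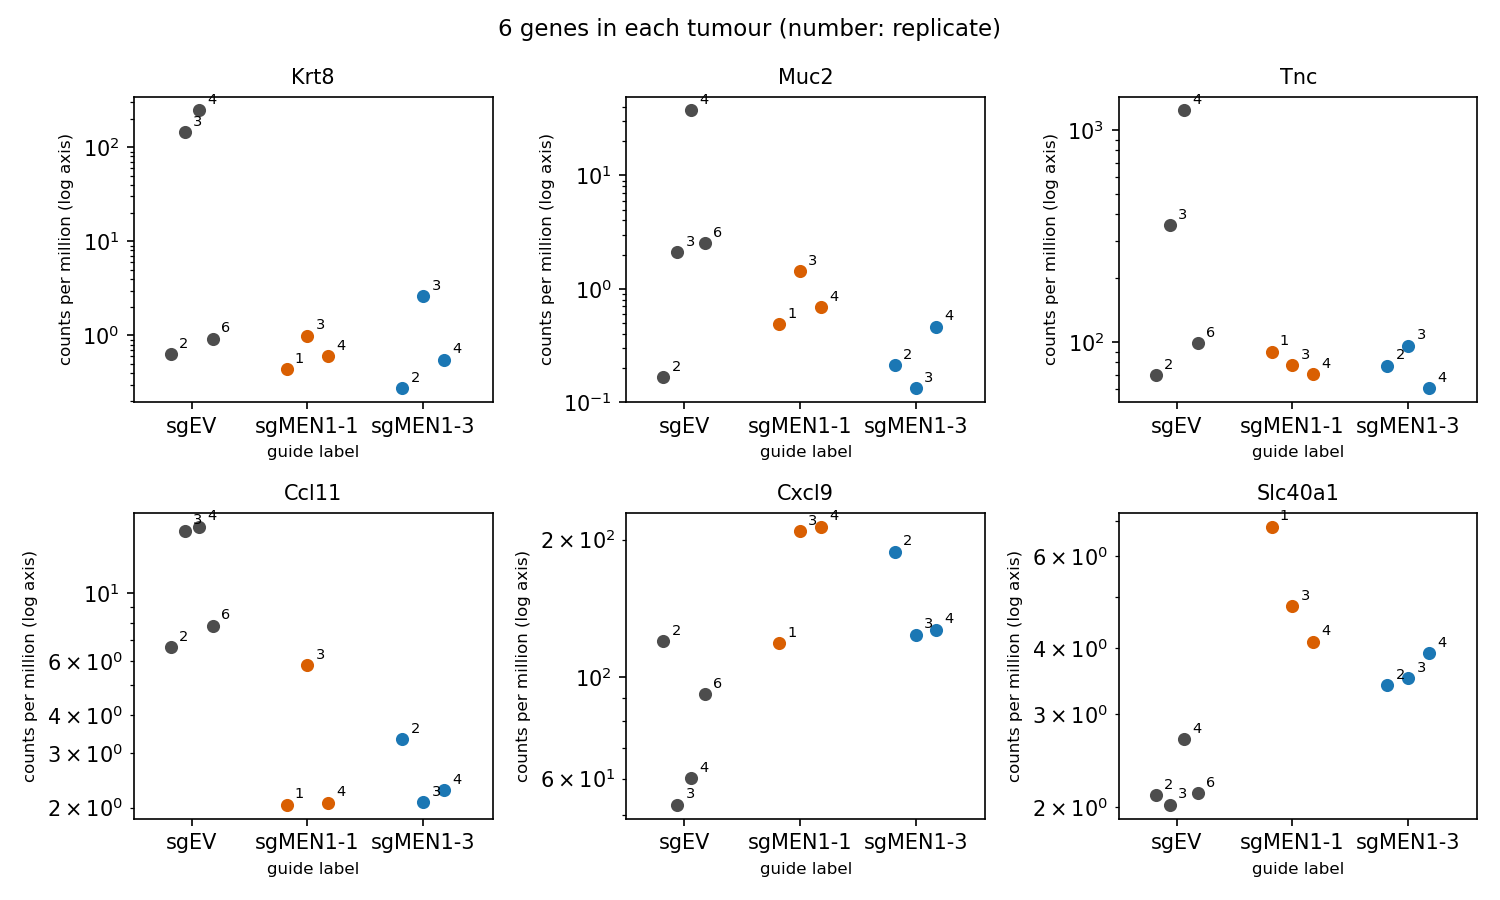
The genes Krt8, Muc2, Tnc, Ccl11, Cxcl9 and Slc40a1 in each tumour, in CPM on a log axis (vertical) by group (horizontal); points are tumours. Krt8 lies at 146 and 246 CPM in sgEV replicates 3 and 4 and at 2.61 CPM or less elsewhere, while Slc40a1 lies at 2.02 to 2.69 CPM in sgEV and 3.41 to 6.81 CPM in sgMEN1 tumours.

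Genes tied to menin itself were not called. The menin-MLL complex list had a median log2 fold change of 0.07 (9 of 15 positive, adjusted p = 0.0930). Its methyltransferase Kmt2a stood at 158 ± 42.0 CPM in sgEV and 195 ± 33.0 in sgMEN1 tumours. Another member of the list, Paxip1, stood at 65.1 ± 11.7 and 76.7 ± 6.36 CPM. Known menin-MLL targets had a median of -0.09 (13 of 19 negative, adjusted p = 0.389). Hoxa10, a homeobox gene kept active by MLL complexes, stood at 13.2 ± 2.33 and 10.7 ± 1.30 CPM (-0.31, SE 0.15), and Cdkn2c, a cell-cycle inhibitor that menin activates, at 35.8 ± 10.8 and 46.0 ± 9.20 CPM (0.35, SE 0.18).

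Of the remaining lists none was called with all tumours and no block. Chemokines and cytokines had a median of 0.02, a mean of -0.02 and a test pointing higher (adjusted p = 0.591), with Cxcl14 at 81.3 ± 59.6 and 28.2 ± 15.2 CPM and the alarmin Il33 at 82.1 ± 78.3 and 23.3 ± 8.08. Immune checkpoint genes had a median of 0.19 (adjusted p = 0.0915; called higher with the replicate block, adjusted p = 0.00538), with the PD-1 ligand Pdcd1lg2 at 31.8 CPM in sgEV replicate 4 and 3.88 ± 1.25 in sgMEN1 tumours. NF-kappaB targets had a median of 0.05 (adjusted p = 0.178). The p53 targets had a median of -0.09 (16 of 19 negative, adjusted p = 0.101), and Trp53inp1 stood at 12.01 ± 2.98 and 8.17 ± 1.35 CPM (-0.57, SE 0.17). The MYC and ribosome biogenesis genes had a median of -0.02 (adjusted p = 0.496). Hypoxia and glycolysis genes had a median of -0.03 but a test pointing higher (adjusted p = 0.946), with the glycolytic regulator Pfkfb3 at 29.4 ± 8.62 and 42.0 ± 7.84 CPM. Wnt targets had a median of -0.07 (adjusted p = 0.554), with Lef1 at 26.5 ± 20.1 and 13.1 ± 3.17 CPM. Immediate early genes had a median of -0.02 and a mean of 0.01 with a test pointing higher (adjusted p = 0.432), and Klf4 stood at 202 ± 24.9 and 251 ± 30.9 CPM. B and plasma cell genes had a median of -0.04 and a mean of -0.25 with a test pointing higher (adjusted p = 0.375). Within that list the immunoglobulin constant gene Ighm stood at 17.3 ± 2.77 and 23.5 ± 6.07 CPM, and Igkc at 141 CPM in sgEV replicate 3 against 1.08 to 1.81 CPM in the other sgEV tumours. Mast cell, basophil and eosinophil genes had a median of -0.03 and a mean of -0.07 with a test pointing higher (adjusted p = 0.299). Skeletal muscle (median -0.11, adjusted p = 0.557; called higher with the replicate block, at 0.91, adjusted p = 0.0320), adipocyte (0.21, adjusted p = 0.349), peripheral nerve (-0.17, adjusted p = 0.432) and erythroid genes (0.05 with a test pointing lower, adjusted p = 0.946) were likewise not called with no block. Keratinocyte and skin genes were negative in 5 of 5, with a median of -0.47 (adjusted p = 0.432), and Lgals7 stood at 257 ± 154 and 133 ± 36.9 CPM.

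Each guide was also set against sgEV alone, to ask whether both show the same change. Interferon-gamma, MHC class I and II, T cell, neutrophil, cell-cycle and cholesterol lists were called higher, and colon epithelium lower, with either guide, but only the neutrophil list was kept with both guides leaving out each tumour. Type I interferon, cytotoxic lymphocyte and macrophage genes were called higher, and fibroblast and matrix genes lower, with sgMEN1-1 and not with sgMEN1-3, and stress-response genes lower with sgMEN1-3 and not with sgMEN1-1. Nucleic acid sensing and checkpoint genes were also called with sgMEN1-1 alone, and endothelium with sgMEN1-3 alone. Between the guides the matrix (adjusted p = 0.0572), nucleic acid sensing (adjusted p = 0.114), checkpoint (adjusted p = 0.216) and endothelium lists (adjusted p = 0.695) were not called. None of these calls held with an estimated correlation (smallest adjusted p 0.535 and 0.857). The sgMEN1-1 contrast gave 0 genes in edgeR (1077 at an unadjusted p under 0.05, 407 higher and 670 lower), 0 in limma-voom (1005 unadjusted) and 24 in DESeq2. The unadjusted edgeR count was 2992 without sgEV replicate 2, 634 without sgEV replicate 3, 515 without sgMEN1-1 replicate 1 and 682 without sgMEN1-1 replicate 4, and without sgEV replicate 2 edgeR called 4 genes. Among the DESeq2 genes, chosen after their values were seen, Slc40a1 had a log2 fold change of 1.22 (adjusted p = 0.00249), Dnase1l3 of 1.75 (adjusted p = 0.00249) and Ifitm1, an interferon-induced membrane protein, of -0.92 (adjusted p = 0.00913). The kinase Camk2d, also chosen so, stood at 140 ± 10.2 CPM in sgEV and 205 ± 25.7 in sgMEN1-1 tumours. The sgMEN1-3 contrast gave 0 genes in edgeR (813 unadjusted, 310 higher and 503 lower), 0 in limma-voom (790 unadjusted) and 2 in DESeq2, Crabp1 (-3.33, adjusted p = 0.000533) and Ccl11 (-2.18, adjusted p = 0.00235). The unadjusted edgeR count there was 2649 without sgEV replicate 2 and 416 without sgMEN1-3 replicate 4.

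Camera called 16 lists with sgMEN1-1, 13 higher and 3 lower, with 2 genes past the threshold adjusted over the list alone and 0 lists with an estimated correlation. Type I interferon genes had a median log2 fold change of 0.57 (32 of 33 positive, adjusted p = 1.42e-08; adjusted p = 0.535 with an estimated correlation) and the interferon-gamma list one of 0.89 (24 of 26 positive, adjusted p = 1.61e-08; adjusted p = 0.535 with an estimated correlation). Fibroblast genes were negative in 19 of 20, with a median of -0.58 (adjusted p = 3.06e-06; adjusted p = 0.535 with an estimated correlation). The fibroblast list scored -0.75, 0.27 and -0.81 in sgMEN1-1 replicates 1, 3 and 4, of which replicate 3 lay inside the sgEV range of 0.09 to 0.62. The matrix remodelling list had a median of -0.24 (adjusted p = 0.00657; adjusted p = 0.535 with an estimated correlation). Immune checkpoints had a median of 0.26 (adjusted p = 0.0356; adjusted p = 0.535 with an estimated correlation). The other lists called with sgMEN1-1 were MHC class I and II, nucleic acid sensing, mitotic, DNA replication, cholesterol, T cell, cytotoxic, macrophage and neutrophil genes, higher, and colon epithelium, lower (adjusted p = 1.82e-06 to 0.0157; adjusted p = 0.535 to 0.606 with an estimated correlation). In this contrast skeletal muscle had a median of 0.57 and a mean of 0.61 with a test pointing lower (adjusted p = 0.659). With sgMEN1-3 camera called 11 lists, 9 higher and 2 lower, with 2 genes adjusted over the list alone and 0 lists with an estimated correlation. Cholesterol genes were positive in 19 of 19, with a median of 0.42 (adjusted p = 2.04e-10; adjusted p = 0.857 with an estimated correlation). Interferon-gamma genes had a median of 0.69 (24 of 26 positive, adjusted p = 0.000108; adjusted p = 0.906 with an estimated correlation), while the type I list was not called (0.14, adjusted p = 0.132). Stress-response genes were negative in 20 of 20, with a median of -0.20 (adjusted p = 0.000372; adjusted p = 0.857 with an estimated correlation). The other lists called with sgMEN1-3 were MHC class I and II, DNA replication, mitotic, T cell, neutrophil and endothelial genes, higher, and colon epithelium, lower (adjusted p = 0.000372 to 0.0182; adjusted p = 0.857 to 0.927 with an estimated correlation). The list scores of 3 against 4 tumours can reach an exact permutation p of 0.0286, and the smallest found was 0.0571 with sgMEN1-1 and 0.114 with sgMEN1-3.

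Leaving out each tumour, a check of these guide calls added after the data were seen, ended many of them. With sgMEN1-1 9 of 16 calls were kept in all fits: both interferon lists, MHC class I, mitotic, DNA replication, macrophage, neutrophil, fibroblast and colon epithelium genes. The MHC class II call was lost without sgMEN1-1 replicate 3 (difference of mean log2 CPM 0.23 instead of 0.56, adjusted p = 0.171), and the difference was 0.27 without sgEV replicate 4. T cells were lost without that sgMEN1-1 tumour (0.20 instead of 0.47, adjusted p = 0.311) or sgEV replicate 4 (0.16, adjusted p = 0.331). Cholesterol and checkpoint genes were each lost without sgEV replicate 3, sgEV replicate 4 or sgMEN1-1 replicate 3 (adjusted p = 0.232 to 0.411 and 0.0772 to 0.232). In these fits, in that order, the cholesterol difference of 0.18 became 0.07, 0.07 and 0.10. The checkpoint difference of 0.25 became 0.21, 0.16 and 0.14. Nucleic acid sensing (adjusted p = 0.0662) and matrix genes (adjusted p = 0.0587) were lost without sgEV replicate 3, and cytotoxic genes without sgEV replicate 4 (0.53 instead of 1.00, adjusted p = 0.0504). Without sgEV replicate 2 the cytotoxic difference was 1.65, that of T cells 0.72, of cholesterol genes 0.30 instead of 0.18 and of neutrophils 0.61 instead of 0.39. Without sgEV replicate 3 it was 0.14 instead of 0.24 for DNA replication, 0.18 instead of 0.30 for macrophages and 0.62 for cytotoxic genes. Without sgEV replicate 4 it was 0.35 instead of 0.60 for MHC class I, -0.61 instead of -1.05 for colon epithelium and 0.23 for neutrophils. The neutrophil difference was 0.24 without sgMEN1-1 replicate 1, and that of T cells 0.75 without sgMEN1-1 replicate 4.

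With sgMEN1-3 only the cholesterol, stress and neutrophil calls, 3 of 11, were kept in all such fits. The mitotic difference of 0.11 became -0.02 without sgMEN1-3 replicate 3 (adjusted p = 0.341), 0.19 without replicate 2 and 0.18 without replicate 4. Its call was also lost without sgEV replicate 3 (adjusted p = 0.0818) or 4 (adjusted p = 0.0907). The interferon-gamma call was lost without sgMEN1-3 replicate 2 (0.33 instead of 0.77, adjusted p = 0.207). Its difference was 1.24 without sgMEN1-3 replicate 3, and 1.21, 0.46 and 0.51 without sgEV replicates 2, 3 and 4. MHC class I (adjusted p = 0.0670 to 0.480), MHC class II (adjusted p = 0.0818 to 0.111) and endothelium (adjusted p = 0.0818 to 0.276) were each lost without sgEV replicate 3, sgEV replicate 4 or sgMEN1-3 replicate 2. T cells were lost without sgEV replicate 4 (adjusted p = 0.526) or sgMEN1-3 replicate 2 (adjusted p = 0.431), and DNA replication without sgEV replicate 3 (adjusted p = 0.114) or sgMEN1-3 replicate 2 (adjusted p = 0.0667). Without sgEV replicate 2 the difference was 0.69 instead of 0.44 for T cells, 0.59 instead of 0.39 for MHC class I and 0.27 instead of 0.17 for DNA replication. The lowest difference leaving out 1 tumour was 0.13 for T cells and 0.06 for endothelium. Without sgEV replicate 3 the DNA replication difference was 0.09. Without sgEV replicate 4 the difference was 0.15 for MHC class I and 0.29 instead of 0.58 for MHC class II. Without sgMEN1-3 replicate 3 it was 0.64 for MHC class I and 0.27 instead of 0.18 for endothelium. The colon epithelium call was kept in 4 of 10 fits. It was lost without sgEV replicate 4 (-0.63 instead of -1.08), any sgMEN1-1 tumour, or sgMEN1-3 replicate 2 or 3 (adjusted p = 0.0593 to 0.129). The sgMEN1-1 tumours are not part of this contrast, and leaving them out can only change the genes tested and the estimated spread. Likewise, with sgMEN1-1 the colon epithelium difference of -1.05 became -0.86 without sgMEN1-3 replicate 2 or 3. These losses therefore need not mean that the call depends on those tumours.

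The guides were then compared with each other, which tests their difference itself. At the preset correlation, tumours labelled sgMEN1-3 had less transcript of macrophage genes than those labelled sgMEN1-1 and more of cholesterol genes. Type I interferon, cytotoxic, stress-response and immediate early genes were called lower too, and fibroblast genes higher, but each of these calls was lost without some tumour. With an estimated correlation 0 of these lists passed (smallest adjusted p 0.873). MHC class II (adjusted p = 0.725), T cell (adjusted p = 0.956) and DNA replication genes (adjusted p = 0.433) were not called. In edgeR 0 genes passed (smallest adjusted p = 0.714), with 1029 at an unadjusted p under 0.05 (564 higher and 465 lower with sgMEN1-3). That count was 652 without sgMEN1-1 replicate 4 and 646 without sgMEN1-3 replicate 4. Limma-voom gave 0 genes (936 unadjusted) and DESeq2 31, 23 higher and 8 lower. Fitted on these 6 tumours alone, edgeR called 13 genes. Of the DESeq2 genes, chosen after their values were seen, Pcdhb17, an adhesion protein of neurons, stood at 14.4 ± 2.15 CPM in sgEV, 8.58 ± 0.615 in sgMEN1-1 and 17.3 ± 2.47 in sgMEN1-3 tumours (DESeq2 log2 difference 1.02, adjusted p = 0.00141). Ifitm1 stood at 118 ± 28.8, 62.6 ± 4.37 and 128 ± 12.9 CPM (1.05, adjusted p = 0.00251), and Porcn, which modifies Wnt ligands, at 21.98 ± 2.22, 13.9 ± 1.26 and 22.4 ± 3.14 CPM (0.70, adjusted p = 0.0285). Ing2, a reader of histone methylation, went the other way, at 20.8 ± 1.01, 25.8 ± 3.03 and 15.7 ± 2.36 CPM (-0.71, adjusted p = 0.0261). For Pcdhb17, Ifitm1 and Porcn the sgMEN1-3 tumours lay near the sgEV tumours. Reads of the Pcdhb paralogs can match several members, and those were not counted.

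Camera called 7 lists between the guides, 2 higher and 5 lower with sgMEN1-3, with 1 gene adjusted over the list alone, in the B and plasma cell list. With an estimated correlation 0 lists passed. Macrophage genes had a median log2 difference of -0.35 (21 of 27 negative, adjusted p = 9.08e-05; adjusted p = 0.873 with an estimated correlation). Type I interferon genes had a median of -0.34 (31 of 33 negative, adjusted p = 0.000233; adjusted p = 0.873 with an estimated correlation), cytotoxic genes one of -0.70 (21 of 22 negative, adjusted p = 0.00266; adjusted p = 0.873 with an estimated correlation) and stress-response genes one of -0.21 (20 of 20 negative, adjusted p = 0.00133; adjusted p = 0.873 with an estimated correlation). Immediate early genes had a median of -0.19 (adjusted p = 0.0449; adjusted p = 0.873 with an estimated correlation). Cholesterol genes were positive in 18 of 19, with a median of 0.25 (adjusted p = 0.000586; adjusted p = 0.873 with an estimated correlation), and fibroblast genes in 17 of 20, with a median of 0.27 (adjusted p = 0.000752; adjusted p = 0.873 with an estimated correlation). An exact permutation test of 3 against 3 tumours cannot go below p = 0.1, which the cholesterol, cytotoxic and macrophage scores reached, as did the uncalled matrix remodelling, keratinocyte and peripheral nerve scores. The called type I interferon, fibroblast and immediate early scores gave an exact permutation p of 0.4 and the stress score 0.2. Leaving out each tumour kept 2 of the 7 calls in all fits, cholesterol and macrophages. The type I list scored 0.65, -0.82 and -0.02 in sgMEN1-3 replicates 2, 3 and 4, and 0.61, 0.41 and 0.34 in sgMEN1-1 replicates 1, 3 and 4. Its difference of -0.52 in mean log2 CPM became -0.14 without sgMEN1-3 replicate 3 (adjusted p = 0.383) and -0.87 without sgMEN1-3 replicate 2. The cytotoxic call was lost without sgMEN1-3 replicate 3 (-0.61 instead of -0.86, adjusted p = 0.0603) and the stress call without sgMEN1-1 replicate 4 (-0.15 instead of -0.23, adjusted p = 0.0717). The fibroblast call was lost without sgMEN1-1 replicate 4 (0.28 instead of 0.47, adjusted p = 0.0717), and the difference was 0.32 without replicate 1 and 0.83 without replicate 3 of that guide. The immediate early call was kept in 4 of 10 fits. It was lost without sgEV replicate 3 or 6, sgMEN1-1 replicate 1 or 4, or sgMEN1-3 replicate 2 or 3 (adjusted p = 0.0507 to 0.344), and the difference of -0.17 became -0.33 without sgMEN1-1 replicate 3, -0.09 without replicate 1 and -0.06 without replicate 4.

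**Figure D4:**
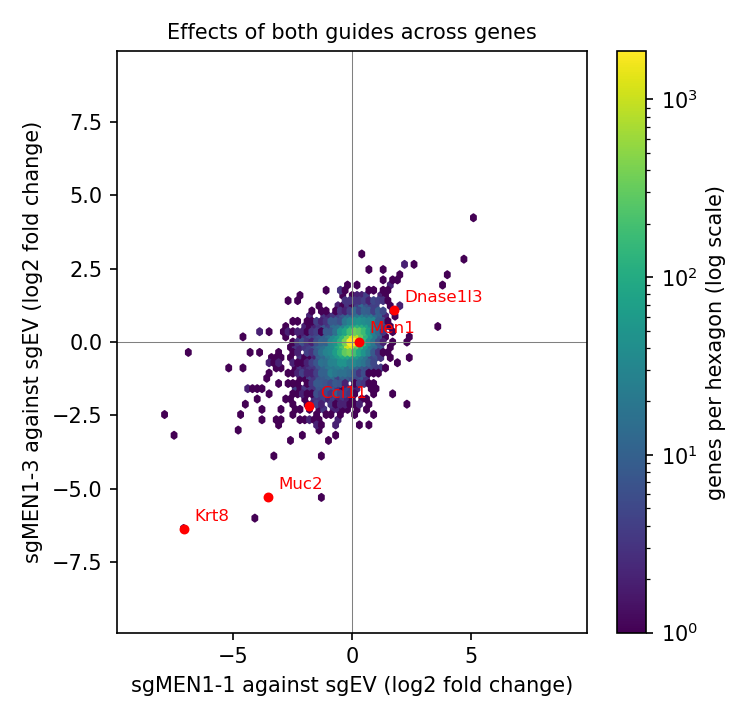
Log2 fold changes of all 17386 tested genes with sgMEN1-1 (horizontal axis) and sgMEN1-3 (vertical axis) against sgEV, coloured by the number of genes on a log scale, with Men1, Krt8, Ccl11, Muc2 and Dnase1l3 marked in red. The effects correlate across genes with r = 0.471.

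The effects of both guides were correlated across genes when measured against the same sgEV tumours, and not when each guide had its own sgEV tumours. Pearson's r was 0.471 and Spearman's rho 0.409, and 66.1% of genes had the same sign with both guides. In 50 simulations with no guide effect the shared sgEV tumours alone gave a mean r of 0.416 (SD 0.0130), a mean rho of 0.385 and 64.0% with the same sign. The covariance of the effects was 0.0997, against 0.0640 in the simulations, a difference of 0.0357. The simulations drew genes independently and gave all groups the same spread, while the sgEV tumours were less alike. The simulated SD may therefore be too small, and the difference does not measure an effect shared by the guides. When the sgEV tumours were split so that each guide had its own pair, r lay between -0.205 and 0.0941 over 6 splits, with a median of -0.0199. The median covariance over these splits was -0.00556. Genes are not independent replicates, so no p-value is given for these correlations.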

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

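Of the tests in this part, those of sample splits, of transcript loss, Men1 counts, cytotoxic content, a wrong label, and epithelium or skin were chosen only after the result was seen, while those of host-cell Men1 and of depth were chosen before.

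Among 109 values compared across the 4 sgEV tumours, 9 had 1 tumour far from the other 3 by Dixon's gap ratio. Chance gives about 1 in 20, here 5.45 of them, for normally distributed values that were not selected. The genes among the 109 values were those named in the text, some of them chosen after their values were seen. The number found therefore cannot be judged against that rate. In sgEV replicate 4 Muc2 stood at 37.4 CPM (others 0.166 to 2.53), Spp1 at 10149 CPM (others 3013 to 4135) and Slc40a1 at 2.69 CPM (others 2.02 to 2.13). In sgEV replicate 3 Igkc stood at 141 CPM (others 1.08 to 1.81). In sgEV replicate 6 Ckm stood at 12.9 CPM (others 0.285 to 0.985). In sgEV replicate 2 Cd274 stood at 79.3 CPM (others 28.6 to 33.6) and the chemokine list scored 0.17 (others -0.09 to -0.07). The Wnt target list scored -0.18 in the same tumour (others 0.16 to 0.21), and its 50 most abundant genes took 13.1% of the counts (others 15.3% to 15.5%).

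Between the guides 7 lists differed, by camera on the difference itself at the preset correlation. The sgMEN1-3 tumours minus the sgMEN1-1 tumours gave score differences of -0.52 for type I interferon genes, 0.27 for cholesterol biosynthesis, -0.23 for the unfolded protein and amino acid stress response, -0.86 for cytotoxic lymphocytes, -0.32 for monocytes and macrophages, 0.47 for fibroblasts and pericytes and -0.17 for immediate early genes. With an estimated correlation none of them passed. The 10 splits of these 6 tumours are too few for a share under 0.05. The real split called 7 lists and 0 genes, 8 of the 10 splits called at least as many lists, and the highest other split called 16 lists and 0 genes. At an unadjusted p under 0.05 the real split gave 1029 genes and the highest other 476. Against sgEV the same count did not stand out. In the main contrast 35 of 100 splits gave at least the real 927 genes (highest other 2786). With sgMEN1-1 16 of 35 splits gave at least the real 1077 (highest other 3859). With sgMEN1-3 19 of 35 gave at least the real 813 (highest other 3653).

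For the lists called against sgEV chance could not be excluded. In the main contrast 23 of 100 splits called at least the real 17 lists (highest other 21), with sgMEN1-1 9 of 35 at least the real 16 (highest other 22) and with sgMEN1-3 17 of 35 at least the real 11 (highest other 19). For genes the real count is 0 in each contrast, so that 100 of 100, 35 of 35 and 35 of 35 splits reach it by construction, which says nothing about chance. The highest other splits gave 33 genes in the main contrast, 703 with sgMEN1-1 and 369 with sgMEN1-3. The split with 703 genes set sgEV replicate 2 and the 3 sgMEN1-1 tumours against sgEV replicates 3, 4 and 6. The split with 369 genes put sgEV replicates 2 and 6 with sgMEN1-3 replicates 2 and 4. Both put sgEV replicate 2 with sgMEN1 tumours, but the second left sgMEN1-3 replicate 3 on the side of sgEV replicates 3 and 4. The split with 33 genes in the main contrast put sgEV replicates 2, 3 and 4 with sgMEN1-1 replicate 3. The samples thus differ in ways that cut across the groups, and not along 1 division alone.

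The first pattern weighed is that Men1 mRNA was not lower in the libraries labelled sgMEN1. The lower 95% limit of the log2 fold change, -0.14, bounds any loss of the transcript from the tumour RNA. It restates the pattern and is no separate test of it. Too few counts are argued against by a counting error of at most 4.42% per library. Host cells, which carry intact Men1, might fill a gap, but over the 6 sgMEN1 tumours Men1 followed the mean leukocyte score only loosely (Pearson r = 0.334, exact p = 0.494; Spearman 0.6, exact p = 0.242), and r was 0.000141 without the 2 tumours farthest from the median. With 6 tumours this stays open. An edit that stops translation but spares the mRNA stays open too and was not tested, since the files hold no reads or protein.

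The next pattern is the higher interferon-gamma list in the libraries labelled sgMEN1. Depth is argued against, since thinning every library to the lowest total kept 101% of the mean log2 CPM difference (0.97 against 0.96). A difference in cytotoxic lymphocyte content between tumours may account for part of it. A regression on that score within groups left 56.1% of the difference, from 0.96 (SE 0.55) to 0.54 (SE 0.21), which does not decide. A wrong label of sgEV replicate 2 cannot be judged by its Men1 level, 25.6 CPM, since Men1 does not separate the groups. The protocadherin beta family, described below, scored -0.00432 in this tumour. The other sgEV tumours scored -0.0168 to 0.234, sgMEN1-1 tumours -0.758 to -0.525 and sgMEN1-3 tumours 0.379 to 0.620. These values argue against the tumour carrying either Men1 guide, as far as a family picked for its difference between the guides can show. Without that tumour the interferon-gamma difference is 1.39. An effect of the Men1 guides stays open, since the call did not hold with an estimated correlation (adjusted p = 0.580).

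The last pattern is high Krt8 in sgEV replicates 3 and 4. Whole colon epithelium of the host is argued against by the median of the other 16 colon epithelium genes, at most 0.375% of the Krt8 level, and by Epcam, abundant in that tissue, at 0.0237 and 0 CPM. Skin is argued against by the median keratinocyte gene, at most 0.0651%, and by its abundant keratins Krt14 (0.095 and 0 CPM) and Krt5 (0 and 0.0266 CPM). Some members of these lists did go with Krt8, namely Krt18 (44.8 and 83.8 CPM), Lgals7 (330 and 433 CPM, 91.5 to 187 elsewhere) and, in replicate 4, Muc2 (37.4 CPM) and Cdx2 (6.33 CPM), while Krt20 (94.1 to 156 CPM) and Lgals4 (14.2 to 27.8 CPM) were present in all 10 tumours. A partial epithelial change in the CT26 cells of those tumours may remain as an explanation, and no biological one was tested, since the tumours share the label sgEV with replicates 2 and 6.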

How the results depend on the processing

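The fits without the muscle-rich libraries, those leaving out 1 library for lists called with a guide or between guides, robust quasi-likelihood and the permutation of list scores were chosen after seeing the data. Where values moved, the cause was not tested. Men1 kept its sign and stayed uncalled in every alternative (log2 fold change 0.06 to 0.28 leaving out 1 library). The 0 genes of the main contrast became 5 with DESeq2 and 2 with no filter (Krt8 and Ccl11, chosen after seeing their values), and stayed 0 under each other alternative. With sgMEN1-1 they became 24 with DESeq2, 2 with the replicate block (Serpina3g and Cxcl9) and 0 to 4 leaving out 1 library, the 4 without sgEV replicate 2 (Atp10a, Fgfr1, Tnnt2 and Ddah2), all chosen after seeing their values. With sgMEN1-3 DESeq2 called 2. Between the guides DESeq2 called 31 and edgeR on the compared groups 13. The 17 called lists became 0 with an estimated correlation, with fry and with permutation, 11 with sgMEN1-3 alone, 16 with sgMEN1-1 alone, 19 with the block (stress lost, adjusted p = 0.103; checkpoints, matrix remodelling and skeletal muscle gained), 17 with RLE, 16 without the muscle-rich libraries and 11 to 20 leaving out 1 library (11 without sgMEN1-3 replicate 2, 20 without sgEV replicate 2). The labels give replicate numbers no meaning, so the numbers were used as a block in alternative fits only. Of the 7 same-number pairs 4 had deviations correlated over 0.1 (-0.0428 to 0.331). Between groups, the pairs with different numbers that passed 0.1 stood at 0.121, 0.133 and 0.168. Of 8 libraries 6 correlated best with a library of their own number, a hint from the data of some pairing. With the block the main contrast gave 1483 genes at an unadjusted p under 0.05 in edgeR instead of 927, and still 0 past the threshold. Among lists called in either fit, directions reversed for the stress list with sgMEN1-1 alone (0.000730), for monocytes and macrophages with sgMEN1-3 alone (-0.0204) and leaving out 1 library (0.0120 to 0.214, lowest without sgEV replicate 3), for mitotic genes with sgMEN1-3 leaving out 1 library (-0.0203 to 0.187, lowest without sgMEN1-3 replicate 3), and for skeletal muscle with the block (0.907, adjusted p = 0.0320). Without the muscle-rich libraries 4 calls were lost: nucleic acid sensing (adjusted p = 0.0787), stress (0.901), monocytes and macrophages (0.0548) and dendritic cells (0.109). The guide correlation of 0.471 became 0.525 under the stricter filter, and with split sgEV pairs 0.0717, 0.0173, -0.0572, -0.205, -0.104 and 0.0941. Of 2826 alternative values of 150 named genes 2819 kept their side of the threshold, 7 passed it and 51 had another sign. Of 630 list values 516 were the same, 22 became called, 88 lost the call and 4 reversed. In all 32 had another direction, such as MYC and hypoxia lists with sgMEN1-1 alone and keratinocytes with sgMEN1-3 alone. Leaving out 1 library kept 148 of 160 list calls with sgMEN1-1, 87 of 110 with sgMEN1-3 and 60 of 70 between the guides.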

Other observations

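All tests of this part were chosen after their results were in view, since each relation was noticed in these data before it was tested; the condition that a mast cell difference must hold leaving out each tumour was added after its value was seen.

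The interferon-gamma score of the tumours rose with their cytotoxic lymphocyte score, an RNA measure that does not count cells. Cytotoxic T and natural killer cells are the main makers of interferon-gamma, and the lists share 0 genes. Across the 10 tumours the scores correlated with Pearson r = 0.905 (permutation p = 0.00057, adjusted p = 0.00855 over 15 cell type lists, 100000 resamples) and Spearman rho = 0.842 (permutation p = 0.00395, adjusted p = 0.0402). Without sgEV replicates 3 and 4, the tumours farthest from the median, r was 0.729. With group means removed r was 0.941, and among the 6 sgMEN1 tumours 0.830, where peripheral nerve (0.833) and erythroid scores (0.792) came as near. Neutrophil (r = 0.824), monocyte and macrophage (0.793) and dendritic cell scores (0.784) went along with it, and T cell (0.758) and endothelium scores (0.747) by Pearson's r only (Spearman adjusted p = 0.109 for each), but B and plasma cells did not (-0.0729). Colon epithelium gave r = -0.816, but -0.379 without sgEV replicates 3 and 4, 0.0352 among the sgMEN1 tumours and a Spearman adjusted p = 0.131. For mast cells, basophils and eosinophils r was 0.566, lower by 0.339 (0.259 to 0.568 leaving out 1 tumour), which leaves open whether they follow less. Differences from the other leukocyte scores were not tested, so the cytotoxic score is not shown to follow most closely. A candidate explanation is that the interferon-gamma signature of a tumour reflects how many cytotoxic lymphocytes entered it, whichever guide it carried; staining for CD8 and interferon-gamma in sections of further tumours would test it.

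The protocadherin beta genes moved together between the guides. These neighbouring genes share a control region and encode adhesion proteins of neurons. Pcdhb7, Pcdhb12, Pcdhb17 and Pcdhb19 were seen first, among the DESeq2 genes. The other 13 tested members were then examined as a set, and camera with an estimated correlation (0.0599) gave an unadjusted p of 0.000490. These 13 are neighbours of the 4 seen and were measured in the same tumours, so this p is not independent support. All 17 tested members, of 22 in the files, were higher with sgMEN1-3 than with sgMEN1-1, also with RLE, with a median log2 difference of 0.93 (0.89 for the other 13), and 12 had an unadjusted p under 0.05. The family score was -0.53, -0.54 and -0.76 in sgMEN1-1 replicates 1, 3 and 4, 0.46, 0.38 and 0.62 in sgMEN1-3 replicates 2, 3 and 4, and -0.02 to 0.23 in sgEV tumours. The score difference of 1.09 had an exact permutation p = 0.1, the smallest that 10 splits allow. The guides lay on opposite sides of sgEV in the family score, though not in each member. Pcdhb5 averaged 0.904 CPM in sgMEN1-3 and 0.978 in sgEV tumours, and Pcdhb4 0.193 in sgMEN1-1 and 0.124 in sgEV tumours. The pattern may reflect a difference between the cells made with each guide, which several independent lines per guide would test. An effect of menin is not excluded, since the loss of menin with each guide was not measured. Reads shared between members were not counted, so single members are uncertain.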
